A study of Rattus norvegicus with 12 samples.

How the data were processed

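The samples were pancreatic islets of Sprague Dawley rats, isolated with collagenase and a Histopaque gradient per the labels. There were 4 groups of 3 libraries, control and IUGR at 2 and at 10 weeks of age. Per the labels, RNA with an integrity number above 7 was depleted of ribosomal RNA and made into stranded libraries. The submitters' processing notes name TopHat2 2.0.9, bedtools and the genome builds rn5 and mm9, without saying what each was used for. The counting rule, the strand setting and the annotation release are not given in the sources used here.

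The deposited table held raw counts per Ensembl rat transcript, whole numbers that sum to a different total in each library, with no normalization. It had 30309 transcripts under 25888 gene symbols. Several transcripts were listed for 2724 symbols, and 153 transcripts with over 100 counts had the same counts as another transcript of the gene, so a read can have been counted more than once. No count was found in any library for 1517 transcripts. The only rat reference at hand was a gene table of another assembly, so no positions are given. Totals ran from 30.4 to 64.2 M counts (M, mega) per library.

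Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, 1 fit of 4 groups with robust quasi-likelihood dispersions, and the quasi-likelihood F test. P-values were adjusted by the method of Benjamini and Hochberg over the 20733 transcripts tested (17361 symbols), and an adjusted p under 0.05 passed. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. The comparisons were IUGR against control at each age, the difference between these effects, and 10 against 2 weeks in each group. The library totals, the scaled CPM and the share of counts in the acinar list and in Ins1 and Ins2 were computed per library, with 95% Wilson intervals for shares of single libraries. For genes with 1 to 3 counts in a group, the ratio of rates was given with an exact 95% Clopper-Pearson interval on the counts. A gene with 0 counts in a whole group was compared with a floor of 3 counts per library.

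Lists of genes for pancreatic cell types, beta cell functions and cell processes were fixed before the data were examined, as were the rule for naming genes and the alternatives below unless said otherwise. There were 38 lists with 883 entries, of which 851 were found. The 37 lists with at least 3 tested members were tested with camera of limma 3.58.1 on the same fit with a preset correlation of 0.01, two-sided, adjusted over the lists. A list of sex-linked transcripts had too few members tested. Camera was also run with the correlation estimated from the data and fry as a test of direction. Members of a list were in addition adjusted over the list alone.

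In each comparison the rule for naming genes took up to 12 genes higher and 12 lower with the largest log2 fold change among those past the threshold. It asked for a mean log2 CPM of at least 1, groups that did not overlap (not asked for the difference between ages) and a gene symbol that is not a locus name or accession. It added the 4 members of each list with the smallest p and a set of islet genes named whether or not they passed, of which the text gives a part. Some genes that the rule takes are not reported here. Where a symbol had several transcripts, the one with the highest mean count was named. Counts of calls are over transcripts.

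The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, an adjusted p under 0.1, the replicate number as a block, the mean log2 CPM of the acinar list as a covariate, the 20 most abundant transcripts and the acinar list left out, only the 6 libraries of a comparison, and each library left out in turn. After the data had been seen, 4 more were added. They were 1 transcript per symbol, both 10-week control libraries with an acinar share above 40% left out, and the estimated correlation in this fit and in that with the covariate. The fit without both leaves 1 control library at 10 weeks, whose spread was assumed to be that of the other groups.

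The steps were tested on simulated counts with 200 transcripts changed in each comparison. At a 4-fold change between 82% and 98% were called, and at a 2-fold change between 35% and 69%. The changed transcripts were taken only from those above a minimum mean CPM, so these shares do not cover transcripts with fewer counts. False calls were 11 of 171 for IUGR at 2 weeks, 2 of 153 at 10 weeks and 9 of 126 for the difference between ages. They were 12 of 173 for age in controls and 9 of 173 for age in IUGR islets. In these runs transcripts were drawn independently of one another and the acinar level did not vary between libraries. The shares called may therefore be too high for the real libraries. Among simulated transcripts that followed only the acinar level, 92% were called without the covariate and 0% with it by edgeR. With the covariate 37.5% of those with a 4-fold group effect were called. The covariate was the very level from which these transcripts were made, so the 0% was fixed in advance. It does not show how well the covariate removes acinar effects in the real libraries. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library and no column of the table was left out of the main test.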

Results

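RNA was counted in pancreatic islets of Sprague Dawley rats that had been growth restricted before birth and of control rats. Intrauterine growth restriction (IUGR) was brought about by tying off the uterine artery on both sides in dams at embryonic day 18. Litters of the controls were culled to 8 pups. Islets were taken at 2 weeks and at 10 weeks of age, which gave 4 groups of 3 libraries that the labels call biological replicates. The labels do not say whether islets of several animals or litters were pooled, nor the sex of the animals. The spread between libraries may therefore not cover that between litters. The question was how islet RNA differed between IUGR and control animals at each age, and how it changed with age in each.

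The deposited table gave raw counts for 30309 transcripts of 25888 gene symbols. Control replicates 1 to 3 at 2 weeks held 45.3, 44.6 and 44.4 M counts (M, mega). The IUGR replicates at 2 weeks held 51.2, 46.0 and 44.0 M. At 10 weeks the control replicates held 64.2, 39.6 and 62.2 M and the IUGR replicates 30.4, 34.1 and 35.0 M. Of the transcripts, 20733 with enough counts were tested.

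The libraries differed in how much of their RNA came from acinar cells, which make digestive enzymes and surround the islets in the pancreas. Transcripts of a list of acinar genes fixed in advance took 28.9% ± 11.7 of counts (SD, n = 3) in controls at 2 weeks and 6.71% ± 2.52 (SD, n = 3) in IUGR libraries of that age. At 10 weeks they took 34.8% ± 18.2 (SD, n = 3) in controls and 1.41% ± 0.862 (SD, n = 3) in IUGR libraries. The share varied within the 10-week controls, from 14.0% (95% Wilson interval 14.0 to 14.0) in replicate 2 to 47.5% (47.5 to 47.5) in replicate 3. These intervals cover counting error only. In both ages the lowest control share lay above the highest IUGR share. Ins1 and Ins2, the insulin genes, together took 2.75% ± 1.27 and 4.54% ± 0.242 of counts at 2 weeks in controls and IUGR libraries. At 10 weeks they took 6.59% ± 3.03 in controls and 19.4% ± 0.732 in IUGR libraries (SD, n = 3 each). Of the counts left after the acinar list was set aside, Ins1 and Ins2 held 9.82% ± 2.37 in 10-week controls and 19.7% ± 0.604 in 10-week IUGR libraries. Only members of the list were set aside, so amylase transcripts outside it stayed among the counts left. Amylase transcripts took a larger share of counts in every 10-week control library than in any 10-week IUGR library. The control value may therefore be too low and the gap between the groups too wide. Some reads of Ins1 and Ins2, and of the amylases, trypsins, Reg genes and immunoglobulins, could be shared between near-identical copies, so the split between such genes is uncertain.

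**Figure D1:**
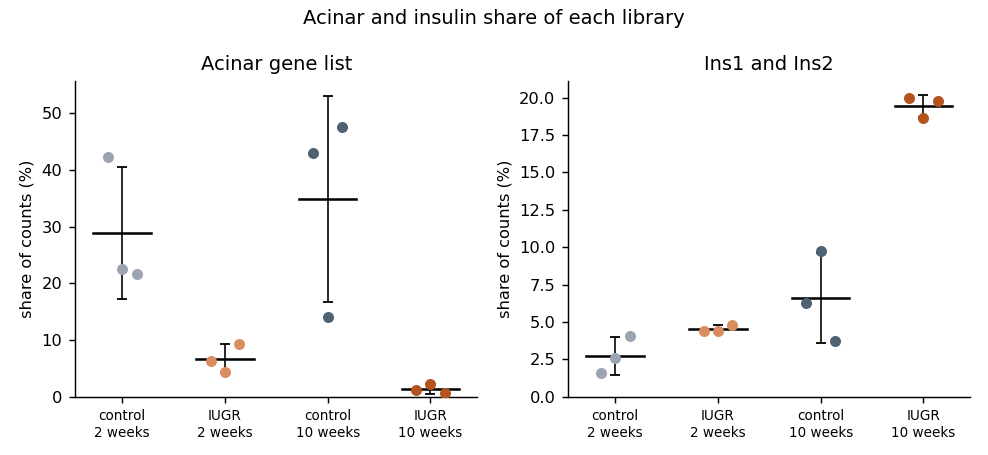
Share of each library's counts, in percent, taken by the acinar gene list (left) and by Ins1 and Ins2 together (right), in the 4 groups. Points are libraries (n = 3 per group), bars the mean and whiskers 1 SD. The IUGR libraries lay between 0.625% and 9.38% acinar counts, all below the control libraries.

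The first comparison asked how IUGR and control islets differed at 2 weeks. By the list test with its preset correlation, 17 lists were higher and 4 lower in IUGR islets. The acinar gene list was among those lower, and the glycolysis, matrix, nerve and fat cell lists were among those higher. None of the lists passed with an estimated correlation (adjusted p = 0.551 to 0.559 for those named). With the acinar level as a covariate the acinar, matrix and nerve lists did not pass either. Gpd1, a cytosolic glycerol-3-phosphate dehydrogenase, rose (log2 fold change 1.89 ± 0.39, adjusted p = 0.0430, with ± as the standard error here and below, n = 3 per group). Scd1, which makes monounsaturated fatty acids, rose by a log2 fold change of 1.69 ± 0.28 (adjusted p = 0.0288), and Ppy, the pancreatic polypeptide hormone, by 1.32 ± 0.30 (adjusted p = 0.0471). Pnlip, pancreatic lipase, fell (log2 fold change -3.41 ± 0.74, adjusted p = 0.0442).

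The other increases named by the rule were those of Prss35, Apln (the peptide apelin), Kif5a (a neuronal kinesin), Epha5 (an ephrin receptor), Actg2 (a smooth muscle actin), Ifi27, Agt (angiotensinogen), Lrrc10b and Vcan (the matrix proteoglycan versican), with log2 fold changes from 1.19 to 1.48. The other decreases were those of Nccrp1, Pla2g1b (a pancreatic phospholipase), Slc16a5, Aqp8 (a water channel), Rnase6, Slc6a11, Gif (gastric intrinsic factor), Tff2 (a mucosal trefoil peptide), Trim50, Car12 (a carbonic anhydrase) and Tmed11, from -3.14 to -2.87.

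Of the 32 acinar genes tested, 4 fell over all transcripts, Pnlip, Pla2g1b, Cuzd1 and Bhlha15, and 30 fell when adjusted over the list alone. Their median log2 fold change was -2.62 (list test, adjusted p = 6.14e-21, and adjusted p = 0.551 with an estimated correlation). Glycolysis genes went the other way. Among 18 tested, 4 rose and none fell, and adjusted over the list alone 11 rose and 1 fell (median 0.39, adjusted p = 5.27e-05, and adjusted p = 0.551 with an estimated correlation). The 4 were Aldoa (0.51 ± 0.10), Pgam1 (0.59 ± 0.12), Tpi1 (0.35 ± 0.08) and Gpi (0.31 ± 0.08). In the hypoxia list, Hif1a, the oxygen-regulated transcription factor subunit, rose by 0.50 ± 0.10 (adjusted p = 0.0429), as did P4ha1 and P4ha2, collagen prolyl hydroxylases, while 17 of 20 genes did not pass and the list test gave an adjusted p of 0.105.

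Lists of stromal, nerve and fat cell genes had medians above 0 at 2 weeks. For 29 mesenchymal and matrix genes the median was 0.63 (adjusted p = 1e-08, and adjusted p = 0.559 with an estimated correlation), with 1 gene, Thy1, risen over all transcripts (1.11 ± 0.26) and 9 adjusted over the list alone. In the neural and Schwann cell list, 3 of 14 rose, namely the neuronal genes Th (2.12 ± 0.49), Stmn2 and Tubb3, and 4 rose when adjusted over the list alone (median 0.90, adjusted p = 8.13e-05, and adjusted p = 0.551 with an estimated correlation). Of 11 adipocyte genes none passed over all transcripts and 9 rose when adjusted over the list alone (median 1.43, adjusted p = 3.38e-06, and adjusted p = 0.551 with an estimated correlation). No member of the endothelial list (median 0.52, adjusted p = 2.23e-05, and adjusted p = 0.559 with an estimated correlation) or of the immediate-early list of fast stress-response genes (median 0.77, adjusted p = 7.92e-05, and adjusted p = 0.559 with an estimated correlation) passed, over all transcripts or adjusted over the list alone. Among 21 imprinted genes, which are expressed from a single parental copy, Rtl1 (0.53 ± 0.12) and Mest (0.70 ± 0.17) rose and 19 did not pass, with 6 higher and 1 lower adjusted over the list alone (median 0.34, adjusted p = 0.0249, and adjusted p = 0.551 with an estimated correlation). Other lists passed with the preset correlation and none with an estimated one (adjusted p = 0.551 to 0.758). Of these, the cytokine (median 0.84, list test adjusted p = 4.8e-06) and macrophage (0.65, 0.00104) lists were higher. So was that of disallowed genes, known to be kept low in adult beta cells (0.35, 0.00756). The ductal (-0.68, 0.00083) and mitochondrial genome (-0.29, 0.000489) lists were lower. All but the ductal median had the opposite sign at 10 weeks. Mean acinar shares in this comparison were 28.9% in control and 6.71% in IUGR libraries.

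Genes of insulin production showed no passing difference at 2 weeks. None of 39 genes of insulin processing and secretion passed, over all transcripts or adjusted over the list alone, although the list test gave a median of 0.29 (adjusted p = 0.0210, and adjusted p = 0.758 with an estimated correlation). The log2 fold change was 0.31 ± 0.38 for Ins1 (adjusted p = 0.610), 0.35 ± 0.35 for Ins2 (adjusted p = 0.527), 0.32 ± 0.21 for the glucose transporter Slc2a2 (adjusted p = 0.317) and 0.13 ± 0.23 for the transcription factor Pdx1 (adjusted p = 0.733). The glucagon gene Gcg stood at 0.68 ± 0.46 (adjusted p = 0.345).

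Across all transcripts, 804 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 345 higher and 459 lower. DESeq2 passed 3219 and put 55.6% of them higher, against 42.9% in the main test. With each library's acinar level as a covariate, in a fit of the 6 libraries alone, and without IUGR replicate 1 or 3, edgeR passed 0 transcripts, with 2626, 6239, 3839 and 4681 at an unadjusted p under 0.05 against 5939 in the main test. It passed 9 without IUGR replicate 2 and 17, 5 and 2350 without control replicates 1, 2 and 3. With the covariate the matrix, neural, imprinted and insulin lists no longer passed. The endothelial and immediate-early list tests turned (medians 0.03 and 0.15), the acinar median became 0.06, and the glycolysis and adipocyte lists still passed. The insulin list also lost its call without control replicate 1 or 2 and the imprinted list without control replicate 1.

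At 10 weeks the same comparison gave many more differences. By the list test with its preset correlation, the acinar, matrix, vessel, stress-response and cytokine lists were lower in IUGR islets and the list of insulin processing and secretion was higher. None of them passed with an estimated correlation (adjusted p = 0.526 to 0.572), and with the acinar level as a covariate the acinar and insulin lists did not pass either. Col1a1, the main chain of collagen I, fell by a log2 fold change of -3.00 ± 0.38 (adjusted p = 0.00116), Ldha, lactate dehydrogenase A, by -1.48 ± 0.22 (adjusted p = 0.00190), and Myc, a growth-related transcription factor, by -2.57 ± 0.29 (adjusted p = 0.000740). Chga, the granule protein chromogranin A, rose by 1.43 ± 0.25 (adjusted p = 0.00324), and Ppy by 1.48 ± 0.31 (adjusted p = 0.00680), with n = 3 per group.

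The decreases named by the rule included those of Cpa4, Amy1a and Amy2a3 (amylases), Tmed11, Tmed6, Reg3a and Reg1a (secreted lectins), Cuzd1, Try10 (a trypsin), Pnlip, Ctrc (chymotrypsin C) and Aldh1l1 (a folate enzyme), with log2 fold changes from -7.82 to -6.08. Of 32 acinar genes, 31 fell, and all 32 when adjusted over the list alone (median -5.74, adjusted p = 1.89e-28, and adjusted p = 0.526 with an estimated correlation). The increases named by the rule included, beside Ppy and Chga, those of Lhfpl5 (a part of hair-cell mechanotransduction, 1.99 ± 0.25), Gnat3 (the taste G protein gustducin), Chst5, Il23r (the interleukin 23 receptor), P2rx2 (an ATP-gated channel), Slc2a5 (a fructose transporter), Zwint (a kinetochore protein), Syndig1, Epha5 and Trpa1 (an irritant-gated channel, 1.41 ± 0.26).

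Among 39 genes of insulin processing and secretion, 21 rose and none fell, and 28 rose when adjusted over the list alone (median 0.61, adjusted p = 7e-11, and adjusted p = 0.526 with an estimated correlation). They included the exocytosis genes Snap25 (0.80 ± 0.16) and Syt4 (0.99 ± 0.22) and the incretin receptor Glp1r (0.53 ± 0.18). Ins1 and Ins2 themselves did not pass, at 0.70 ± 0.38 (adjusted p = 0.188) and 0.73 ± 0.35 (adjusted p = 0.143). Of 18 beta cell transcription factors, 10 rose, among them Rfx6 (0.92 ± 0.15), Isl1 (0.88 ± 0.20), Neurod1 (0.73 ± 0.20) and Pdx1 (0.68 ± 0.23), and Tcf7l2 fell (-1.66 ± 0.34), with 12 higher and 1 lower adjusted over the list alone (median 0.53, adjusted p = 0.000162, and adjusted p = 0.526 with an estimated correlation). Of 15 genes known to be higher in adult than in newborn beta cells, 9 rose, or 11 adjusted over the list alone (median 0.70, adjusted p = 1.46e-06, and adjusted p = 0.526 with an estimated correlation). Examples were the prolactin receptor Prlr (0.77 ± 0.17), the zinc transporter Slc30a8 (0.75 ± 0.20) and the peptide Ucn3 (0.68 ± 0.21). Mean acinar shares here were 34.8% in control and 1.41% in IUGR libraries.

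Genes known to be kept low in adult beta cells, the disallowed genes, fell as a group: 24 of 26, or 25 adjusted over the list alone, with none higher (median -1.32, adjusted p = 4.94e-18, and adjusted p = 0.494 with an estimated correlation). Beside Ldha they included hexokinase 1, Hk1 (-1.44 ± 0.18), the growth factor binding protein Igfbp4 (-1.43 ± 0.17) and the Fc receptor Fcgrt (-1.31 ± 0.16), which other pancreatic cell types express as well. Of 29 mesenchymal and matrix genes, 20 fell, or 25 adjusted over the list alone (median -1.23, adjusted p = 8.06e-15, and adjusted p = 0.526 with an estimated correlation). They included Col1a1, Col1a2 (-2.20 ± 0.29), the matrix protease Mmp2 (-2.09 ± 0.26) and the growth factor receptor Pdgfra (-1.50 ± 0.23). Of 23 endothelial genes, 20 fell, or 21 adjusted over the list alone (median -0.93, adjusted p = 3.23e-09, and adjusted p = 0.526 with an estimated correlation), with VE-cadherin, Cdh5 (-1.43 ± 0.28), Plvap (-1.13 ± 0.23) and von Willebrand factor, Vwf (-1.49 ± 0.30). The vessel growth factor Vegfa, by contrast, rose (log2 fold change 0.55 ± 0.12, adjusted p = 0.00958). The angiogenic list as a whole was lower, with 10 of 20 fallen, or 12 adjusted over the list alone (median -0.68, adjusted p = 0.000162, and adjusted p = 0.526 with an estimated correlation), including the receptors Tek (-1.19 ± 0.24) and Ephb4 (-1.38 ± 0.16).

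Stress-response and inflammation lists were lower too by the list test. Of 28 immediate-early genes, 20 fell, or 24 adjusted over the list alone (median -1.27, adjusted p = 2.85e-09, and adjusted p = 0.526 with an estimated correlation), with Myc, Jund (-1.07 ± 0.19) and Zfp36 (-1.98 ± 0.37). Of 39 cytokine and NF-kB genes, 21 fell over all transcripts, and adjusted over the list alone 24 fell and 1 rose (median -1.22, adjusted p = 6.97e-06, and adjusted p = 0.572 with an estimated correlation). Among those that fell were the inducible nitric oxide synthase Nos2 (-3.41 ± 0.41) and the chemokines Cxcl1 (-3.01 ± 0.65) and Ccl11 (-2.61 ± 0.54). In the macrophage and myeloid list 3 of 24 fell, or 2 adjusted over the list alone (median -0.80, adjusted p = 0.00992, and adjusted p = 0.697 with an estimated correlation). This list lost its call without control replicate 2 (median -0.60, adjusted p = 0.122) and without IUGR replicate 1 (median -0.63, adjusted p = 0.0618). Over all lists named at 10 weeks, leaving out 1 library ended 3 calls, those of the macrophage list included. In the antioxidant list 11 of 30 fell and 3 rose, the same numbers when adjusted over the list alone (median -0.18, adjusted p = 0.00840, and adjusted p = 0.526 with an estimated correlation). The metallothionein Mt2A (-3.76 ± 0.36) and Txnip (-2.20 ± 0.25) were among those lower and superoxide dismutase 1, Sod1 (0.60 ± 0.10), among those higher.

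Of 26 IGF and insulin signalling genes, 10 fell and none rose, also when adjusted over the list alone (median -0.23, adjusted p = 6.04e-05, and adjusted p = 0.526 with an estimated correlation). They included Igf1 (-1.85 ± 0.18), its binding protein Igfbp5 (-2.82 ± 0.34) and the receptor adaptor Grb10 (-1.98 ± 0.17). Of 13 transcripts of the mitochondrial genome, 4 rose, or 5 adjusted over the list alone (median 0.29, adjusted p = 0.000652, and adjusted p = 0.526 with an estimated correlation), among them ND3 (0.70 ± 0.15), Mt-nd6 and Mt-nd4l, subunits of respiratory complex I. The cell cycle inhibitor Cdkn1a fell (log2 fold change -2.19 ± 0.20, adjusted p = 0.000496), while the proliferation list did not pass in the main test (adjusted p = 0.561, median -0.27). Its direction depended on the setting. Without control replicate 2 its median was 0.16 (list test, adjusted p = 0.0201), and with the acinar level as a covariate the list passed as lower.

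**Figure D2:**
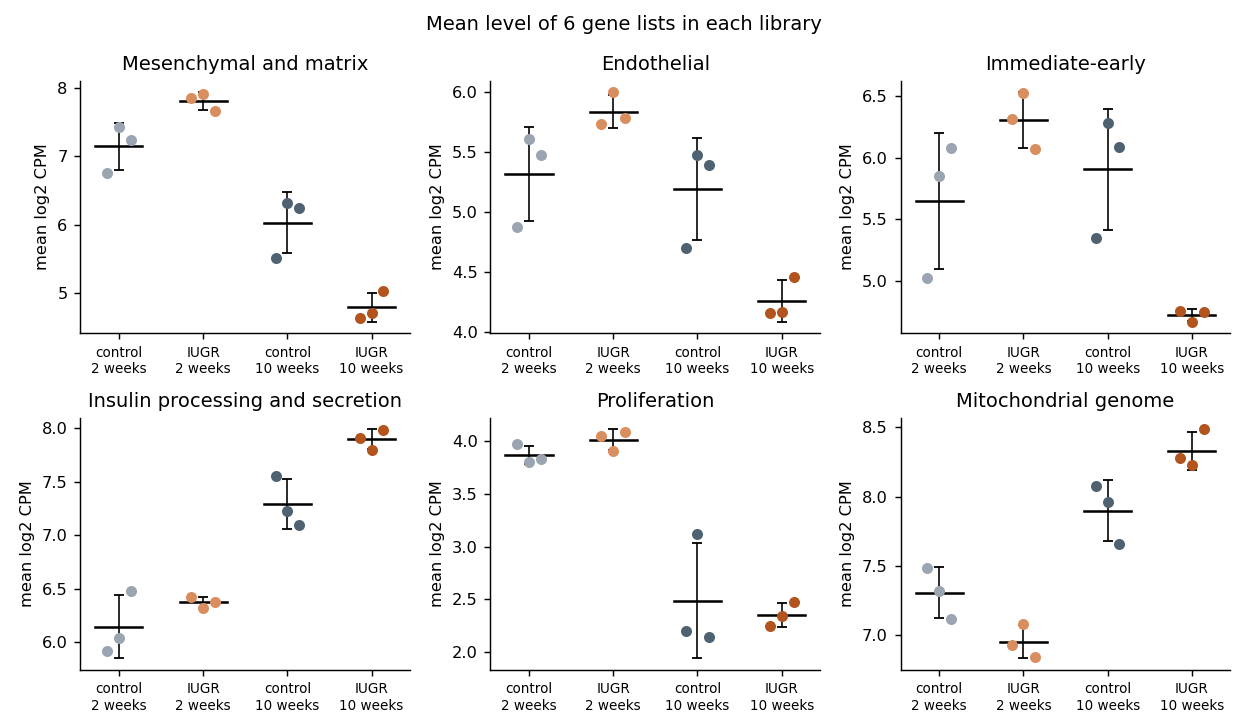
Mean log2 CPM (TMM-scaled) over the tested genes of 6 gene lists, in each library. Points are libraries (n = 3 per group), bars the group mean and whiskers 1 SD. At 10 weeks the matrix list stood between 4.63 and 5.02 in IUGR libraries and between 5.51 and 6.32 in control libraries.

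In edgeR's quasi-likelihood test 5776 transcripts passed at 10 weeks, 2570 higher and 3206 lower. With the acinar level as a covariate 1696 passed, of which 1003 were among the 5776, and 26.4% were higher against 44.5% in the main test. Of the genes named for this comparison, those below among other observations included, 51 then lost their calls, among them the risen ones of the insulin, transcription factor and maturation lists, and Amy2a3 and Reg1a turned to 0.21 and 0.44. Of the lists named for this comparison, 4 lost their calls. Among them were the insulin list (median 0.36, list test adjusted p = 0.0525) and the transcription factor and mitochondrial lists. The acinar and antioxidant medians turned to 0.01 and 0.10. Without 1 library the count ran from 2971 (control replicate 3, acinar share 47.5%) to 7021 (control replicate 1, acinar share 43.0%), with 3785 without IUGR replicate 1. A fit of the 6 libraries alone passed 3472, and Chst5, Cpa4, Glp1r, Gnat3, Il23r, Neurod1, Pdx1, Slc30a8, Ucn3 and Vegfa each lost the call without at least 1 of the 6 libraries. Of the genes named for this comparison, 4 lost the call in the fit of the 6 libraries and 2 with the replicate number as a block.

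The next comparison tested the difference itself, the IUGR effect at 10 weeks minus that at 2 weeks. By the list test with its preset correlation, the matrix, vessel, nerve and immediate-early lists had a negative difference and the mitochondrial genome list a positive one. None of them passed with an estimated correlation (adjusted p = 0.342 for each). Vip, a neuropeptide, had a negative difference (log2 difference -6.95 ± 1.13, adjusted p = 0.00471), as did Nefl, a neurofilament protein (-6.03 ± 0.82, adjusted p = 0.00245). Kcna2, a voltage-gated potassium channel, had a positive one (2.26 ± 0.50, adjusted p = 0.0138), and Gipr, the receptor for the incretin GIP, stood at 1.48 ± 0.30 (adjusted p = 0.00975), with n = 3 in each of 4 groups.

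The other negative differences named by the rule were those of Ucma, C1qtnf9, Serpina3n, Pla2g2a, Mcpt1l1 and Cpa3 (mast cell proteases), Wfdc21, Pck1 (a gluconeogenic enzyme), Clca5 and Dhrs9, from -5.74 (Serpina3n) to -4.93 (Cpa3) where counts allowed a fitted value. Ucma and C1qtnf9 had only 2 and 3 counts over the 3 IUGR libraries at 10 weeks, against 57 and 69 in controls, which made control levels 32.7 times (counting interval 8.65 to 277) and 26.4 times (8.67 to 131) the IUGR levels. The other positive differences were those of Lhfpl5, Rgs11, B3galt2, Spag8, Zwint, Prss53, Ccdc30, Kifc2, Bphl and Mt-nd4l, from 1.39 to 1.80.

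By list, 24 of 29 matrix genes passed with a negative difference, or 27 adjusted over the list alone (median -1.82, adjusted p = 1.6e-24, and adjusted p = 0.342 with an estimated correlation). Col1a1 stood at -3.85 ± 0.52 and Mmp2 at -2.35 ± 0.35. For the endothelial list it was 21 of 23, the same number adjusted over the list alone (median -1.45, adjusted p = 1.82e-14, and adjusted p = 0.342 with an estimated correlation), with Cdh5 at -1.97 ± 0.39. In the immediate-early list 22 of 28 passed as negative, and adjusted over the list alone 23 passed as negative and 1 as positive (median -1.79, adjusted p = 4.21e-14, and adjusted p = 0.342 with an estimated correlation). Atf3 stood at -2.85 ± 0.53 and Zfp36 at -3.06 ± 0.51. In the neural and Schwann cell list 11 of 14 passed as negative, or 13 adjusted over the list alone (median -1.87, adjusted p = 2.74e-06, and adjusted p = 0.342 with an estimated correlation), with S100b at -3.40 ± 0.57 and Th at -4.01 ± 0.75. In the disallowed list 21 of 26 passed as negative, or 24 adjusted over the list alone (median -1.51, adjusted p = 8.9e-20, and adjusted p = 0.342 with an estimated correlation), with Ldha at -2.08 ± 0.31. Among transcripts of the mitochondrial genome 6 of 13 passed as positive, or 9 adjusted over the list alone (median 0.67, adjusted p = 2.74e-07, and adjusted p = 0.342 with an estimated correlation). The median IUGR effect on this list was -0.29 at 2 weeks and 0.29 at 10 weeks. Vegfa stood at 0.75 ± 0.18 (adjusted p = 0.0182). For Ins1, Ins2 and Ppy no difference between ages passed (0.39 ± 0.54, 0.37 ± 0.49 and 0.16 ± 0.42).

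**Figure D3:**
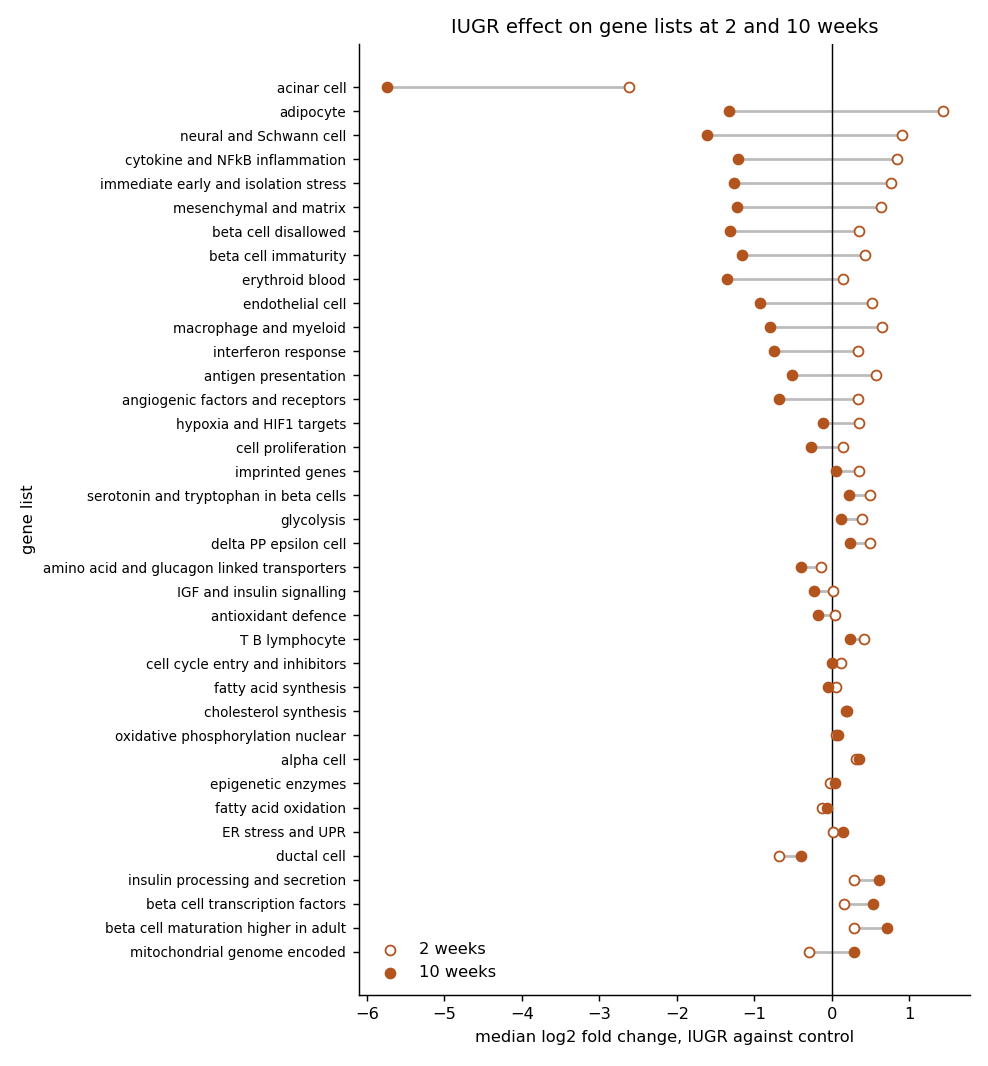
Median log2 fold change of IUGR against control over the tested genes of 37 gene lists, at 2 weeks (open circles) and at 10 weeks (filled circles), with a line joining the ages of each list. Lists are ordered by the difference between ages. The matrix list went from 0.63 to -1.23 and the insulin list from 0.29 to 0.61.

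In all, 2973 transcripts passed this test in edgeR, 824 with a positive and 2149 with a negative difference. With the acinar covariate 4556 passed, of which 2350 were among the 2973, and Cpa3, Dhrs9, Gipr, Mcpt1l1, Pck1, Pla2g2a, Ucma, Vegfa and Wfdc21 lost their calls. So did the antioxidant, transcription factor, erythroid, glycolysis and insulin lists, while Ppy turned to -0.20 and the test of the acinar list turned as well. Counts without 1 library ran from 1759 (without IUGR replicate 2 at 2 weeks) to 4983 (without control replicate 1 at 10 weeks), with 1819 without IUGR replicate 1 at 2 weeks and 1943 without control replicate 3 at 10 weeks. B3galt2, Cpa3, Dhrs9, Mcpt1l1, Pla2g2a, Prss53 and Ucma each lost the call without at least 1 library. Over the fits without 1 library, 5 checks of the lists lost the call as well.

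In control islets, the comparison of 10 with 2 weeks of age asked how islet RNA changed as the animals matured. By the list test with its preset correlation, the beta cell maturation and macrophage lists were higher at 10 weeks, and the proliferation, matrix and imprinted lists were lower. None of them passed with an estimated correlation (adjusted p = 0.206 to 0.516). Ins1 rose by a log2 fold change of 1.96 ± 0.39 (adjusted p = 0.00400), Ins2 by 1.94 ± 0.36 (adjusted p = 0.00272) and Iapp, the co-secreted peptide amylin, by 2.50 ± 0.32 (adjusted p = 0.000407). Igf2, the fetal growth factor, fell by -1.69 ± 0.15 (adjusted p = 9.08e-05) and Mki67, a marker of dividing cells, by -1.76 ± 0.31 (adjusted p = 0.00205), with n = 3 per group.

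The increases named by the rule included those of the immunoglobulin genes Ighg, IGG-2A (8.83 ± 1.95) and IGH-1A (7.40 ± 1.52) and of Igkc. Ighg had no count in any 2-week control library and was at least 1714-fold higher at 10 weeks against a floor of 3 counts per library, but control replicate 2 held 340 CPM and replicates 1 and 3 8.14 and 0.256 CPM. Without that library IGG-2A stood at 4.30, IGH-1A at 5.82 and Igkc at 2.54 instead of 5.19. Reg3a, Reg3g, Reg3b, Trpa1, Serpina3n, Il23r, Mug2 and Pigr (the epithelial receptor that carries antibodies) rose by 4.26 to 6.72. Gif fell (-7.10 ± 0.86), as did the angiotensin receptor Agtr2 (-6.39 ± 0.32), and Vsig1, Car3, Alox15, Tdh, Adipoq (the fat hormone adiponectin), Dlk1 (an imprinted growth regulator), Cldn1, Tex15, Cldn11 and Gnat3 fell by -3.09 to -5.34.

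All 15 maturation genes tested rose, also when adjusted over the list alone (median 1.88, adjusted p = 4.18e-24, and adjusted p = 0.206 with an estimated correlation), with Prlr (3.17 ± 0.18), Slc2a2 (2.37 ± 0.22), Mafa (1.83 ± 0.24) and Ucn3 (1.42 ± 0.22). Of 39 insulin processing and secretion genes 30 rose and 1 fell, with 31 and 1 adjusted over the list alone (median 1.17, adjusted p = 2.3e-22, and adjusted p = 0.258 with an estimated correlation). Of 30 unfolded protein response genes 16 rose, or 18 adjusted over the list alone (median 0.58, adjusted p = 1.58e-08, and adjusted p = 0.400 with an estimated correlation), such as the chaperone Dnajb9 (1.59 ± 0.15). Of 39 proliferation genes 35 fell, the same number adjusted over the list alone (median -1.38, adjusted p = 4.18e-24, and adjusted p = 0.258 with an estimated correlation), such as Melk (-2.35 ± 0.25) and E2f1 (-1.69 ± 0.19). Of 29 matrix genes 20 fell and 1 rose, with 22 and 1 adjusted over the list alone (median -0.90, adjusted p = 2.14e-11, and adjusted p = 0.440 with an estimated correlation), such as Col3a1 (-2.35 ± 0.33). Of 21 imprinted genes 11 fell and 4 rose, with 12 and 4 adjusted over the list alone (median -0.94, adjusted p = 2.23e-05, and adjusted p = 0.206 with an estimated correlation), with Cdkn1c, a cell cycle inhibitor, at -2.78 ± 0.25.

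Antigen presentation genes rose in 13 of 19, or 16 adjusted over the list alone (median 1.55, adjusted p = 2.23e-05, and adjusted p = 0.516 with an estimated correlation). So did 21 of 34 interferon response genes, the same number adjusted over the list alone (median 0.82, adjusted p = 5.85e-06, and adjusted p = 0.516 with an estimated correlation). B2m, the light chain of class I molecules, stood at 1.82 ± 0.25. So did 14 of 24 macrophage and myeloid genes, or 17 adjusted over the list alone (median 1.27, adjusted p = 5.94e-05, and adjusted p = 0.516 with an estimated correlation). For lymphocytes it was 6 of 24, the same number adjusted over the list alone (median 2.41, adjusted p = 0.000524, and adjusted p = 0.564 with an estimated correlation). Control replicate 2 at 10 weeks stood apart, with a mean log2 CPM of 2.09 over lymphocyte genes against -1.08 and -0.23 in replicates 1 and 3. Without it the lymphocyte list lost its call (median 0.40, adjusted p = 0.0825) and the antigen presentation list kept it (median 0.92, adjusted p = 0.000907). Of 15 alpha cell genes 8 fell and 2 rose, with 9 and 2 adjusted over the list alone (median -1.07, adjusted p = 0.00690, and adjusted p = 0.516 with an estimated correlation). Gcg stood at -1.32 ± 0.46 (adjusted p = 0.0487).

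Of all transcripts tested by edgeR, 6693 passed, 3563 higher and 3130 lower at 10 weeks. Without control replicates 1 and 3 at 10 weeks, whose acinar shares were 43.0% and 47.5%, 3690 passed, and a fit of the 6 libraries alone passed 3448. Gcg and Reg3b lost their calls without at least 1 library, and Gcg also with another scaling. Gnat3 was among those that lost the call without both of those control libraries. Ins1 was 1 of 2 that lost it in the fit of the 6 libraries (edgeR, adjusted p = 0.0541). With 1 transcript per symbol 1 of the genes named lost its call, and 1 with the replicate number as a block.

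In IUGR islets the comparison of the ages shares no library with that in controls. By the list test with its preset correlation, the insulin and mitochondrial genome lists were higher at 10 weeks, and the matrix and proliferation lists were lower. None of them passed with an estimated correlation (adjusted p = 0.239 to 0.383). Ins1 rose by 2.34 ± 0.40 (adjusted p = 0.000510), Ins2 by 2.31 ± 0.37 (adjusted p = 0.000319) and Prlr by 3.77 ± 0.19 (adjusted p = 9.32e-07). Col1a1 fell by -6.29 ± 0.45 (adjusted p = 3.1e-06), Ldha by -2.25 ± 0.23 (adjusted p = 1.94e-05) and Dlk1 by -7.40 ± 0.56 (adjusted p = 4.06e-06), with n = 3 per group.

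The increases named by the rule included those of IGH-1A (6.46 ± 1.46), Glycam1, Cr2 (a complement receptor of B cells), Trpa1, Il23r, Tmem35, Chst5, Fam135b, Prlr, Abhd3 and Tpd52l1, down to 3.52. Like control replicate 2, IUGR replicate 2 stood apart at 10 weeks on lymphocyte genes. Its mean log2 CPM was 2.01 against 0.14 and 0.46 in replicates 1 and 3. Without it IGH-1A stood at 5.40 and Glycam1 at 5.84, both still past the threshold, and Cr2 at 3.40 (adjusted p = 0.109). The decreases included those of Car3 (-10.48 ± 1.35), Agtr2 (-8.17 ± 0.35), Dlk1, Adamts19, Alox15, Adipoq and the mast cell proteases Cma1, Mcpt1l1, Cpa3 and Tpsab1, up to -6.47. Ucma and C1qtnf9 fell from 1371 and 1182 counts over the 2-week libraries to 2 and 3 over the 10-week libraries, so that the 2-week levels were 410 times (counting interval 113 to 3389) and 236 times (80.4 to 1140) the 10-week levels.

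All 15 maturation genes rose, also when adjusted over the list alone (median 2.31, adjusted p = 7.11e-17, and adjusted p = 0.204 with an estimated correlation). So did all 13 transcripts of the mitochondrial genome, also when adjusted over the list alone (median 1.37, adjusted p = 2.23e-09, and adjusted p = 0.262 with an estimated correlation). Of 39 insulin processing and secretion genes 36 rose and 1 fell, the same numbers adjusted over the list alone (median 1.57, adjusted p = 4.06e-18, and adjusted p = 0.262 with an estimated correlation). Of 29 matrix genes 28 fell, also when adjusted over the list alone (median -2.97, adjusted p = 2.84e-24, and adjusted p = 0.239 with an estimated correlation), with Col1a2 at -5.36 ± 0.33. In the disallowed list 25 of 26 fell, also when adjusted over the list alone (median -1.95, adjusted p = 1.79e-14, and adjusted p = 0.204 with an estimated correlation). For the endothelial list it was 21 of 23, the same number adjusted over the list alone (median -1.63, adjusted p = 3.06e-08, and adjusted p = 0.481 with an estimated correlation), with Cldn5 at -4.03 ± 0.37. Proliferation genes fell in 37 of 39, or 38 adjusted over the list alone (median -1.85, adjusted p = 2.05e-13, and adjusted p = 0.383 with an estimated correlation), with Mki67 at -2.28 ± 0.32. Of 21 imprinted genes 15 fell and 4 rose, the same numbers adjusted over the list alone (median -1.45, adjusted p = 0.000178, and adjusted p = 0.204 with an estimated correlation), with Grb10 at -3.41 ± 0.18 and Igf2 at -1.81 ± 0.15. The acinar list, at mean shares of 6.71% and 1.41% of counts, fell in 19 of 32 genes, the same number adjusted over the list alone (median -2.18, adjusted p = 0.00822, and adjusted p = 0.771 with an estimated correlation). With the acinar level as a covariate its test turned (median -0.16).

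**Figure D4:**
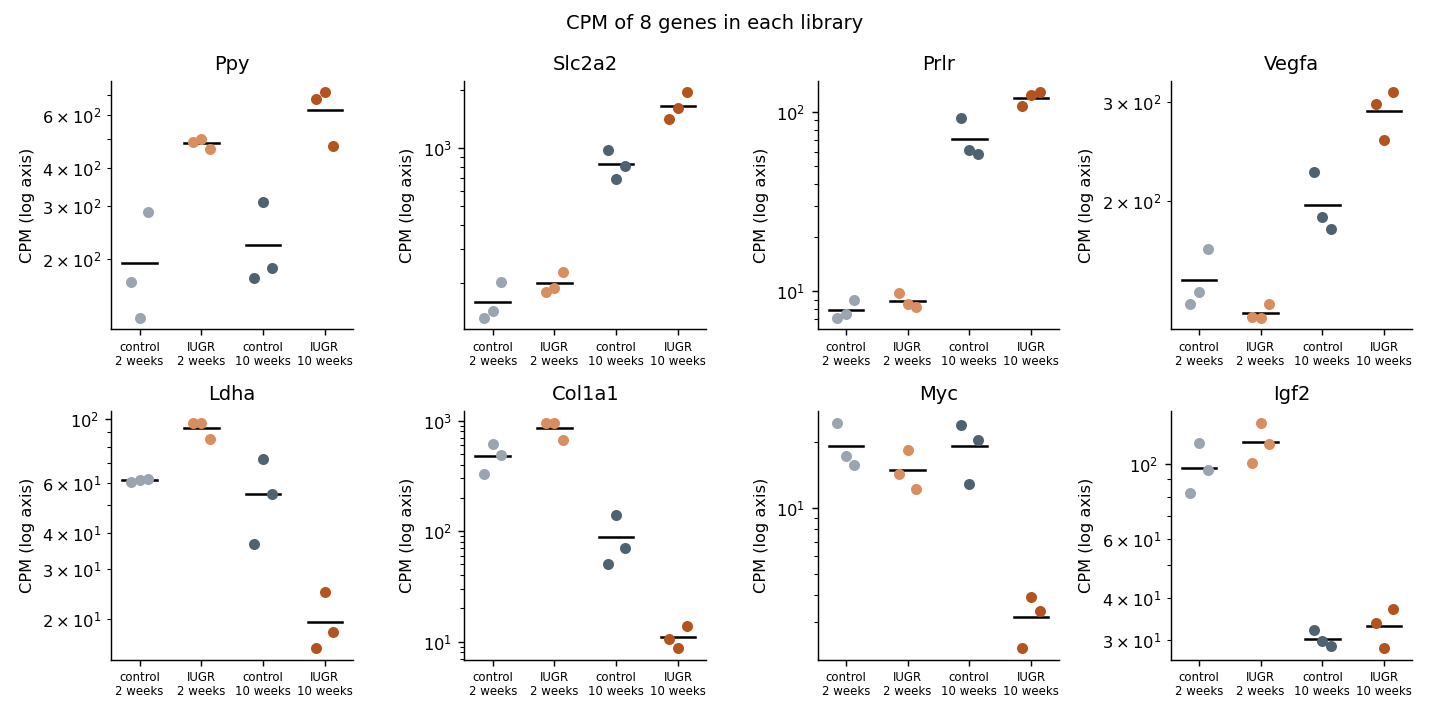
CPM (TMM-scaled) of 8 genes named in the text in each library, on a log axis. Points are libraries (n = 3 per group) and bars the group mean. Ldha was lowest in the 10-week IUGR libraries and Ppy higher in IUGR than in control libraries at both ages.

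By edgeR 11717 transcripts passed, 5661 higher and 6056 lower at 10 weeks. Over the alternatives the count ran from 9786 (with 1 transcript per gene symbol, of 17360 tested) to 13225 (at an adjusted p under 0.1), and Cr2 and Glycam1 lost their calls without at least 1 library.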

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

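The tests of the patterns weighed here were chosen only after the results were seen, apart from the covariate fit and the test of the difference between ages, which were planned as analyses. The 10 splits are all that 6 libraries allow, and the 100 are the real one and others drawn from those possible.

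A different IUGR effect at 10 than at 2 weeks, by edgeR's test of the difference itself, is why each value in this paragraph and the next stands here. It was found for 2973 transcripts. Lists with a negative median log2 difference were the acinar (-3.01), adipocyte (-2.50), cytokine (-2.28), neural and Schwann cell (-1.87), matrix (-1.82), immediate-early (-1.79), disallowed (-1.51), endothelial (-1.45), beta cell immaturity (-1.37), macrophage (-1.37), antigen presentation (-1.19), angiogenic (-1.17), erythroid (-1.04), interferon (-0.99), glycolysis (-0.31), antioxidant (-0.28) and IGF signalling (-0.25) lists. Lists with a positive median were the mitochondrial genome (0.67), beta cell transcription factor (0.46), beta cell maturation (0.41) and insulin (0.34) lists. All of these passed camera with the preset correlation and none with an estimated one (adjusted p between 0.342 and 0.579).

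Among genes, the log2 difference was 2.26 for Kcna2, 1.80 for Lhfpl5, 1.79 for Rgs11, 1.67 for B3galt2, 1.65 for Spag8, 1.56 for Zwint, 1.50 for Prss53, 1.49 for Ccdc30, 1.48 for Gipr, 1.45 for Kifc2, 1.41 for Bphl, 1.39 for Mt-nd4l and 0.75 for Vegfa. It was -6.95 for Vip, -6.03 for Nefl, -5.74 for Serpina3n, -5.70 for Pla2g2a, -5.58 for Mcpt1l1, -5.34 for Wfdc21, -5.23 for Pck1, -5.08 for Clca5, -5.03 for Dhrs9 and -4.93 for Cpa3. Further values were -4.01 for Th, -3.85 for Col1a1, -3.40 for S100b, -3.06 for Zfp36, -2.85 for Atf3, -2.35 for Mmp2, -2.08 for Ldha and -1.97 for Cdh5. The fitted values of -6.02 for Ucma and -6.00 for C1qtnf9 depend on how counts near 0 are handled, since 1 group held 2 and 3 counts.

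Of 100 splits of the libraries that kept the ages apart, 1, the real one, gave as many as 2973 transcripts with a different effect, and the highest of the others gave 1634. That share does not settle whether chance is excluded, since the 92 splits that mixed the 10-week groups added the difference between these groups to the spread within them and gave at most 1 transcript. The 7 others that kept the 10-week groups whole gave 265 to 1634. For the other comparisons the 10 splits of 6 libraries, of which 1 was the real one, are too few for a share under 0.05. The real and highest other counts were 804 and 0 for IUGR at 2 weeks, 5776 and 0 for IUGR at 10 weeks, 6693 and 455 for age in controls and 11717 and 0 for age in IUGR islets. Every other split here mixed the groups compared and so added their difference to the spread within groups. Its low count therefore says nothing about chance.

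The levels of matrix, endothelial and immediate-early genes in IUGR islets at 10 weeks had a median log2 fold change of -1.14 over the 80 members, with a median standard error of 0.26. With the acinar level as a covariate the median was -2.03 (median standard error 0.52), so it did not shrink. Whether acinar RNA in the control libraries was the whole cause is not settled by this fit, since the groups' acinar shares do not overlap at this age. With the covariate 41 members passed as lower on their own against 60 without it. All 3 lists then passed with the preset correlation (highest adjusted p = 5.49e-16) but not with an estimated one (highest adjusted p = 0.432), as without the covariate (adjusted p = 0.526). The acinar and endothelial lists did not fall by the same amount. The acinar median differed from the endothelial one by -4.81, with an SD over members of 1.002 and 0.36. Whether all cells outside the islet fell by a common amount is not settled, since the endothelial list does not separate cells inside the islet from those outside it. A loss of stromal and vascular cells, in the animal or during isolation, and lower expression in such cells both stay open, since no cells were counted, and so does an effect of growth restriction itself, which was not tested.

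The higher insulin processing and secretion genes at 10 weeks had a median of 0.61 with a median standard error of 0.20. Without the 2 control libraries with acinar shares above 40% the median was 0.75. That fit leaves 1 control library at 10 weeks, replicate 2, with an acinar share of 14.0%. It therefore does not settle whether those 2 libraries were the whole source. Dilution of islet RNA by acinar RNA in controls remains a candidate explanation. With the acinar level as a covariate the median fell to 0.36 while the median standard error rose to 0.47, which ended the list's call (adjusted p = 0.0525, and 0.779 with an estimated correlation) and those of all 21 members. The shares of the groups do not overlap at this age, so the effects cannot be told apart, and an effect of growth restriction on beta cells is open and untested.

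The 804 differences at 2 weeks may in part follow the acinar share. With the covariate none passed, although 79.5% kept their sign and at least 50% of their log2 fold change. Among those higher the median went from 0.58 to 0.43 and its median standard error from 0.12 to 0.17, and among those lower from -0.87 to -0.54 and from 0.19 to 0.22, so both a smaller effect and a wider error ended the calls. The acinar shares of the groups do not overlap at 2 weeks either, so acinar RNA and growth restriction cannot be told apart for these transcripts. The effect of growth restriction was not tested apart from it.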

How the results depend on the processing

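Leaving out both 10-week controls with over 40% acinar counts, using 1 transcript per symbol, and the estimated correlation in the fits with the covariate and without both controls were chosen after the data had been seen. The other alternatives were planned. Over all alternatives 3208 of 3722 checks of the 228 gene results kept direction and side of the threshold, 506 lost the call, 2 gained one and 6 turned. The 3722 include checks at an adjusted p under 0.1, which reuses the main fit with a looser threshold. In the order of the comparisons below, 44, 71, 36, 44 and 33 such checks all kept both. No call is lost and no direction turns there by construction, so for called genes these checks say nothing about stability. Of 1033 checks of 73 list results 779 kept both, 222 lost the call, 4 gained one and 28 turned. Where no other reason is given the cause was not tested.

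For IUGR at 2 weeks (804 transcripts in the main test) edgeR passed 149 with no filter on low counts, which tests more transcripts. It passed 0 with the acinar covariate (2626 at an unadjusted p under 0.05), 0 in a fit of the 6 libraries alone (6239 unadjusted), 3021 at an adjusted p under 0.1 and from 0 to 2350 without 1 library. The 2350 came without control replicate 3 alone, and leaving out any other library left at most 17. DESeq2 passed 3219. For IUGR at 10 weeks (5776) the count was 1696 with the covariate, 3472 in the fit of 6 libraries and 2971 to 7021 without 1 library. For the difference between ages (2973) it was 4556 with the covariate, 4735 at an adjusted p under 0.1 and 1759 to 4983 without 1 library. For age in controls (6693) it was 3690 without both high-acinar controls, 3448 in the fit of 6 libraries and 4552 to 6833 without 1 library, and for age in IUGR islets (11717) 10067 to 10687 without 1 library.

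The lists past the threshold numbered 21, 19, 21, 21 and 20 in the order of these comparisons. With an estimated correlation none passed in any of the 5 comparisons (0 of 37 each), also with the covariate (0 in each) and without both high-acinar controls (0 in each), while fry passed 7, 19, 18, 22 and 24. Fry asks whether the members changed, and camera whether they changed more than other genes, so their counts answer different questions. Of the lists past fry, 5, 17, 15, 18 and 18 also passed camera with the preset correlation. With the covariate 11 lists passed camera with the preset correlation at 2 weeks. Without 1 library they ran from 18 to 21, 20 to 22, 19 to 23, 20 to 24 and 19 to 23.

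Direction turned with the covariate for Amy2a3 (0.21) and Reg1a (0.44) at 10 weeks and for the difference between ages of Ppy (-0.20). The median turned for the acinar list (0.0587) at 2 weeks and the test, not the median, for the endothelial (0.0311) and immediate-early (0.15) lists. At 10 weeks the median turned for the acinar (0.0129), antioxidant (0.10), epigenetic enzyme (-0.27) and fatty acid synthesis (0.32) lists. For the acinar list the median turned in the difference between ages (0.00413), and only the test with age in IUGR islets (-0.16). Without both high-acinar controls the sign turned for the difference between ages of Ppy (-0.32). It also turned at 10 weeks for the epigenetic enzyme (-0.00739) and fatty acid synthesis (0.10) lists. By fry only the test turned, for the epigenetic enzyme list at 10 weeks (median 0.0406 as before). Without 1 library, values whose sign or test turned ran from -0.0109 to 0.30 for Pdx1 at 2 weeks and from -0.23 to 0.54 for Ppy in the difference between ages. At 10 weeks they ran from -0.42 to 0.16 for the proliferation list, from -0.0181 to 0.11 for the epigenetic enzyme list and from -0.0685 to 0.00107 for the fatty acid synthesis list.

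With the replicate number as a block, 1223 transcripts passed for IUGR at 2 weeks and 5563, 3235, 6902 and 11843 in the other comparisons, with 22, 19, 21, 20 and 20 lists. The labels do not say what a number shares. Of 18 pairs with the same number 8 correlated above 0.1 (-0.137 to 0.478, median 0.0826, against -0.0179 for other pairs). In the data 8 of 12 libraries, not all, were closest to their own number. Replicate 2 had the highest mean log2 CPM over lymphocyte genes in every group. It was -0.36 and -0.61 in controls and IUGR at 2 weeks, and 2.09 and 2.01 at 10 weeks. The main test took the libraries to share only a number, but a factor shared by same-numbered libraries stays open. In simulated data only 35% of 2-fold changes in the difference between ages were called. Depth limits transcripts with few counts, of which the filter kept 20733 against 28792 tested without it.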

Other observations

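Genes of red blood cells were lower in IUGR than in control islets at 10 weeks. Of 9 tested, 5 fell, the same number adjusted over the list alone (median log2 fold change -1.36, list test adjusted p = 0.00294, and adjusted p = 0.526 with an estimated correlation, n = 3 per group). They fell with age too. In IUGR islets 8 of 9 fell, the same number adjusted over the list alone (median -3.00, adjusted p = 1.87e-05, and adjusted p = 0.262 with an estimated correlation), with Alas2, the first enzyme of heme synthesis in red cells, at -3.00 ± 0.29. In controls 7 of 9 fell, again the same number adjusted over the list alone (median -1.36, adjusted p = 8.99e-05, and adjusted p = 0.378 with an estimated correlation).

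Among enzymes that modify DNA or chromatin, 10 of 30 fell and 2 rose with age in controls, with 14 and 2 adjusted over the list alone (median -0.27, adjusted p = 0.00285, and adjusted p = 0.408 with an estimated correlation). The methylcytosine dioxygenases Tet1 (-1.04 ± 0.12) and Tet3 (-1.24 ± 0.20) and the DNA methyltransferases Dnmt3a (-0.78 ± 0.11) and Dnmt3b (-1.23 ± 0.20) were among those that fell. Between IUGR and control islets none of 30 passed at 2 weeks (median -0.02, list test adjusted p = 0.230). At 10 weeks 1 rose and 2 fell (median 0.04, mean -0.09, list test adjusted p = 0.724).

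In fat metabolism, Acacb and Dgat2, enzymes of fatty acid and triglyceride synthesis, fell at 10 weeks in IUGR islets (-2.32 ± 0.30 and -1.68 ± 0.30), while Elovl6 and Me1 rose (0.62 ± 0.15 and 0.66 ± 0.18). The list of fatty acid synthesis as a whole showed no common direction (median -0.05, list test adjusted p = 0.981), with 10 of 16 not past the threshold.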
